A study of Mus musculus with 6 samples.

How the data were processed

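Spleens came from adult F1 females, and per the labels' protocols animals were euthanised by cervical dislocation under anaesthesia, the tissue was snap frozen, RNA was extracted with Trizol and labelled with biotin by the standard Affymetrix procedure. The deposited values are on a log2 scale and the authors brought them to a common scale before deposit, as the values show by array medians between 5.05 and 5.10. Per the submitters' processing notes RMA and MAS5 were used, with no role or version given. Values ran from 1.81 to 14.56, and which of the 2 methods made them is not given in the sources used here. A summary on this scale compresses differences close to background and close to saturation, so that transcripts near 14 can differ by more than their values show. Probes were designed on a reference sequence, and a parental variant under a probe can lower its signal without a change in amount.

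Each sample's group and replicate number were taken from its title. The deposited values covered 45101 probe sets, of which 64 Affymetrix control probe sets were left out of tests, leaving 45037. Platform annotation gave 1 symbol to 34945 of these, several to 932 and none listed here to 9160, and no gene was named from a probe set with several symbols. Of the probe sets with 1 symbol, 34741 matched a gene of the reference annotation of assembly GRCm38.p6 through their gene identifier, and 0 symbols changed. That assembly was used for names and for which genes neighbour each other, and no coordinates are given, since the files name no genome build. No 2 arrays held the same values: between 121 and 181 probe sets had identical values in any pair.

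Differences were tested per probe set with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the deposited log2 values of all 6 arrays, with no covariate and Benjamini-Hochberg adjustment over all 45037 probe sets. Files were read with data.table, version 1.17.8, and statmod 1.5.0 served the robust variance fit. The threshold was an adjusted p of 0.05. Gene-level results used, for each of 18193 genes, the probe set with the highest mean among those with 1 symbol, with adjustment over genes. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1, so significance rests on the spread that limma pools across probe sets. Each probe set has 4 residual degrees of freedom.

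Lists of genes were fixed before the data were examined: 24 lists, of which 23 were tested with limma's camera at a preset correlation of 0.01 between genes, in lists with at least 5 measured genes, adjusted over the lists. They covered B cells, T cells, NK cells, plasma cells and immunoglobulins, red pulp macrophages and monocytes, neutrophils, dendritic cells, erythroid cells, megakaryocytes and platelets, cell cycle, interferon response, MHC class I and class II presentation, extracellular matrix, pancreatic acinar cells, adipocytes, immediate early genes, glucocorticoid response, heat shock, metastasis modifier genes, known strain variants, ribosomal proteins, oxidative phosphorylation and, untested as a list, a sex check. Klrd1 and Thy1 each stand in 2 lists. At the preset correlation 11 lists passed, 8 higher in the AKR/J cross and 3 in the DBA/2J cross. With a correlation estimated from the 6 arrays 0 passed, and with limma's fry, which tests whether a list's genes move one way on balance, 5 passed (T cells, erythroid cells, interferon response, dendritic cells and metastasis modifier genes).

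Named genes followed a rule fixed before the data were examined. From probe sets with 1 symbol past the threshold, with the 3 arrays of one cross all above those of the other, 1 probe set per gene was taken (the smallest p), and the 12 genes with the largest difference in each direction were named, passing over clone and predicted names. For each list, up to 4 members past the threshold with the smallest adjusted p were named, or the member with the smallest p where none passed, and all members of the strain variant, metastasis modifier and sex check lists could be named. Further list members, probe sets and neighbouring genes named as examples or exceptions were chosen after their values were seen.

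Pairs of neighbouring differing genes were compared with 10000 random draws of as many measured genes. Alternatives fixed in advance were median centring of each array, quantile normalization, leaving out probe sets below the 40th percentile of mean level, a trended and robust variance model, array weights, the replicate number as a block, leaving out each array in turn, the mean of a gene's probe sets, the set tests above, and leaving out gene family pairs. An alternative pseudocount was planned for linear values only and was not run. The mean of the pancreatic acinar genes as a covariate was added after the data were seen.

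The limma procedure was tested on simulated data for this comparison, with 45037 probe sets drawn from each probe set's own mean and residual spread and 50 of them changed at each of 4 sizes. At a change of 0.58 on the log2 scale 42% were recovered, at 1.00 86%, and at 2 and at 3 98%, and 7 of the 169 probe sets called were unchanged. The simulated noise was independent between probe sets, and far fewer probe sets were called than the 4688 in the real comparison. These rates therefore do not carry over to the real arrays.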

Results

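Gene expression was measured in the spleen of adult F1 females from 2 crosses that share the inbred parent FVB/NJ. The other parent was AKR/J in 3 animals and DBA/2J in 3 animals, and each spleen was hybridised to its own Affymetrix array. The series asks which transcripts differ at baseline between the 2 genotypes. All differences below are AKR/J cross minus DBA/2J cross on the log2 scale, so a positive value is higher in the AKR/J cross. The 6 arrays had medians between 5.05 and 5.10, and values ran from 1.81 to 14.56. Small as they were, differences in median separated the crosses (5.05, 5.06 and 5.08 in the AKR/J cross, 5.10, 5.10 and 5.09 in the DBA/2J cross). The SD of an array's values did so too (2.32 to 2.34 in the AKR/J cross, 2.26 to 2.28 in the DBA/2J cross). Across probe sets, which are not independent replicates, Pearson's r was 0.995 to 0.996 between arrays of the AKR/J cross, 0.988 to 0.994 within the DBA/2J cross and 0.979 to 0.991 between crosses. The values carry no counts or detection calls, so the number of arrays limits the precision. Each label names one spleen, and limma's p-values per probe set and per gene rest on the spread between these samples. That spread is pooled across probe sets or genes. The camera p-values compare a list's genes with the other genes, and those of the neighbour test come from random draws of genes.

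Spleens of the DBA/2J cross had more red cell precursor transcripts and more transcripts of dividing cells, and spleens of the AKR/J cross had more T cell transcripts. These 3 list shifts passed in camera at its preset correlation and not with an estimated correlation (adjusted p = 0.570, 0.570 and 0.259). The Rh blood group gene Rhd stood at 10.34 ± 0.65 in the DBA/2J cross and 7.88 ± 0.39 in the AKR/J cross (mean ± SD, n = 3 each). The T cell coreceptor gene Cd8a stood at 7.46 ± 0.03 and 8.05 ± 0.01. Reg2, which encodes a secreted lectin of the Reg family, was 109-fold higher in the AKR/J cross. Transcripts of pancreatic exocrine cells were close to the top of the range in 5 of the 6 arrays. In all, 4688 of 45037 probe sets passed an adjusted p of 0.05 in limma (10.4%), 2317 of them higher in the AKR/J cross and 2371 higher in the DBA/2J cross. With each array centred on its median, 61.9% of the probe sets past the threshold were higher in the AKR/J cross, against 49.4% as deposited. A difference of at least 1.5-fold was present in 1502 (687 higher in the AKR/J cross, 815 in the DBA/2J cross) and one of at least 2-fold in 512 (171 and 341). With 1 probe set per gene, 3133 of 18193 genes passed (17.2%), 1621 higher in the AKR/J cross and 1512 in the DBA/2J cross. The 3 arrays of one cross all lay above the 3 of the other for 36.1% of probe sets, where chance gives 10%. The probe set count fell to 1001, 1513 and 1164 without replicates 1, 2 and 3 of the AKR/J cross, and was 4793, 1148 and 1253 without replicates 1, 2 and 3 of the DBA/2J cross. It was 781 with the mean of the pancreatic exocrine transcripts as a covariate, a setting chosen after the data were seen. That mean was 5.80 in replicate 3 of the DBA/2J cross and 12.58 to 13.48 in the other arrays. The covariate therefore mostly sets that array apart and is not a check separate from leaving it out.

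Among the 12 named genes with the largest difference toward the DBA/2J cross, several belong to the red cell lineage. Rhd differed by -2.46 ± 0.31 (SE; adjusted p = 0.00586), Rhag, which encodes the Rh-associated glycoprotein, by -2.34 ± 0.28 (adjusted p = 0.00452), and Icam4, a red cell adhesion molecule, by -2.42 ± 0.29 (adjusted p = 0.00454). Trim10, a RING finger gene of erythroid cells, differed by -2.37 ± 0.21 (adjusted p = 0.00159). The claudin gene Cldn13 differed by -2.67, Tmcc2 by -2.55, Ypel4 by -2.29 and Tac2, which encodes the neurokinin B precursor, by -2.21. Of 17 measured genes of the erythroid list, 15 were higher in the DBA/2J cross and 0 in the AKR/J cross, with 17 past the threshold adjusted over the list alone. Examples are Epb42, a protein of the red cell membrane (-1.85 ± 0.21, adjusted p = 0.00421), Alas2, the first enzyme of heme synthesis in red cell precursors (-1.31 ± 0.16, adjusted p = 0.00553), and the erythroid transcription factor Gata1 (-1.50, adjusted p = 0.013). Car1 (-1.34) did not pass, and neither did Hba-a1 (-0.29), whose only probe set with 1 symbol stood at background (2.80 and 3.10) and cannot show alpha globin. The list's median was -1.50, with camera adjusted p = 3.07e-12 at the preset correlation and adjusted p = 0.570 with an estimated correlation. The number of erythroid genes past the threshold was 12 to 16 when any 1 array was left out, and 10 with the pancreatic covariate. Tac2 lost its call without replicate 1 (adjusted p = 0.0708) or 3 (0.0701) of the AKR/J cross and without replicate 2 (0.0787) or 3 (0.0683) of the DBA/2J cross.

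Genes of the cell cycle list moved in the same direction. Of 24 measured, 17 were higher in the DBA/2J cross, 0 in the AKR/J cross and 7 did not pass, and 24 passed adjusted over the list alone. The proliferation marker Mki67 differed by -1.60 ± 0.25 (adjusted p = 0.0103), the cyclins Ccnb2 and Ccna2 by -1.65 ± 0.24 and -1.63 ± 0.28, and the mitotic kinesin Kif11 by -1.32 ± 0.23. The replication helicase genes Mcm2, Mcm3, Mcm4 and Mcm5 had differences of -0.76, -0.66, -0.56 and -0.71 and did not pass. The list's median was -1.09 (camera adjusted p = 1.80e-11), with adjusted p = 0.570 with an estimated correlation. Mean cell cycle scores relative to the 6-array mean were -0.57, -0.27 and -0.78 in the AKR/J cross and -0.00, 0.74 and 0.89 in the DBA/2J cross. The count past the threshold was 2, 13 and 4 without replicates 1, 2 and 3 of the AKR/J cross, 23, 3 and 10 without replicates 1, 2 and 3 of the DBA/2J cross, and 3 with the pancreatic covariate.

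**Figure D1:**
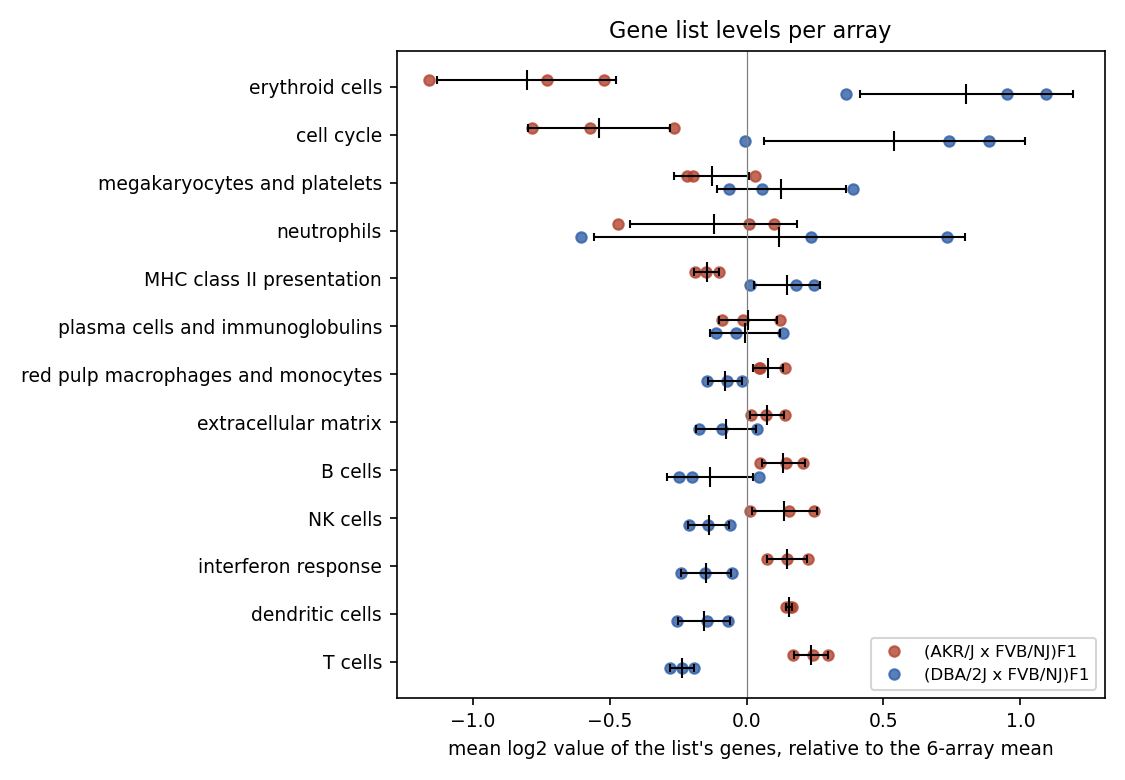
Mean log2 value of each list's genes in each array, relative to the mean of the 6 arrays (points, 1 per array), with the cross mean and SD (bars, n = 3). The erythroid scores lie between -1.16 and -0.52 in the AKR/J cross and between 0.36 and 1.09 in the DBA/2J cross, and the T cell scores lie apart in the opposite direction.

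T cell genes were higher in the AKR/J cross. Of 13 measured T cell genes, 12 were higher in the AKR/J cross and 0 in the DBA/2J cross, also 12 adjusted over the list alone. The coreceptor chains Cd8a and Cd8b1 each differed by 0.59 (SE 0.07 and 0.08, adjusted p = 0.00431 and 0.00704), the scavenger receptor family member Cd5 by 0.69 ± 0.10 (adjusted p = 0.00749) and Cd247, the zeta chain of the T cell receptor complex, by 0.48 ± 0.07 (adjusted p = 0.00916). The cytokine receptor gene Il7r (0.23) did not pass. The list's median was 0.42 (camera adjusted p = 2.28e-08), with adjusted p = 0.259 with an estimated correlation. The count was 7, 8 and 6 without replicates 1, 2 and 3 of the AKR/J cross, 11, 7 and 6 without replicates 1, 2 and 3 of the DBA/2J cross, and 5 with the pancreatic covariate.

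Of 11 B cell genes, 3 were higher in the AKR/J cross: the complement receptor Cr2 (0.45 ± 0.09, adjusted p = 0.0175), the B cell receptor component Cd79a (0.36 ± 0.08, adjusted p = 0.0284) and Ms4a1, which encodes CD20 (0.33 ± 0.09, adjusted p = 0.0438). Adjusted over the list alone, 7 passed, and the median was 0.30 (camera adjusted p = 0.00244, and adjusted p = 0.785 with an estimated correlation). Of 11 NK cell genes, 3 were higher in the AKR/J cross (4 adjusted over the list alone), namely Klrd1, the CD94 subunit of NK receptors (0.97 ± 0.11, adjusted p = 0.00390), the transcription factor Eomes (0.51) and Klra7 (0.23, at a level of 4.26 and 4.02). The NK cell genes Gzma (0.01) and Ncr1 (-0.02) did not pass, and of the 11 values 9 were positive and 2 negative. The NK list had camera adjusted p = 0.0264, with adjusted p = 0.570 with an estimated correlation. Of 8 dendritic cell genes, 3 were higher in the AKR/J cross, also 3 adjusted over the list alone: the lectin Cd209a (0.70 ± 0.07, adjusted p = 0.00347), Siglech of plasmacytoid dendritic cells (0.60) and the transcription factor Zbtb46 (0.59). The dendritic cell list had camera adjusted p = 0.0226, with adjusted p = 0.570 with an estimated correlation. Of the B cell genes, 0, 1 and 0 passed without replicates 1, 2 and 3 of the AKR/J cross, 8, 0 and 0 without replicates 1, 2 and 3 of the DBA/2J cross, and 0 with the pancreatic covariate. In the same order of arrays left out, 2, 1, 2, 2, 1 and 1 NK cell genes and 1, 2, 2, 4, 1 and 2 dendritic cell genes passed. The adjusted p was 0.0838 for the dendritic cell list and 0.132 for the NK list with dim genes left out, and the NK list's adjusted p was 0.0580 without replicate 3 of the DBA/2J cross and 0.0783 with that covariate.

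Among 15 genes of red pulp macrophages and monocytes, 3 were higher in the AKR/J cross (4 adjusted over the list alone) and 0 in the DBA/2J cross. These were Cd5l, a secreted macrophage protein (0.71 ± 0.08, adjusted p = 0.00418), the scavenger receptor Marco (0.66 ± 0.08, adjusted p = 0.00418) and the phosphatidylserine receptor Timd4 (0.73 ± 0.10, adjusted p = 0.00751). All 3 passed whichever array was left out. The red pulp markers Spic, Vcam1 and Hmox1 had values of 0.11, -0.08 and -0.03 and did not pass, and the list as a whole was not called (median 0.05, and -0.01 after quantile normalization, camera adjusted p = 0.110). Without replicate 3 of the DBA/2J cross its camera adjusted p was 0.0370, and with the pancreatic covariate 0.0255. In the plasma cell and immunoglobulin list, 2 of 11 genes passed: the immunoglobulin A constant region Igha was lower in the AKR/J cross (-1.14 ± 0.26, adjusted p = 0.0281) and Derl3, a gene of protein degradation at the endoplasmic reticulum, was higher (0.48 ± 0.13, adjusted p = 0.0395). Adjusted over the list alone, 3 were higher in the AKR/J cross and 1 in the DBA/2J cross, and the list was not called (median 0.18, adjusted p = 0.369). Igha lay past the threshold without replicate 2 of the AKR/J cross or replicate 1 of the DBA/2J cross, and in no other fit with 1 array left out. Derl3 passed without replicate 1 of the DBA/2J cross, where 4 genes of the list were higher in the AKR/J cross, and in none of the other 5 such fits. Of 13 neutrophil genes 0 passed in limma, also 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (median -0.20, camera adjusted p = 0.369), and the one with the smallest p was Elane, neutrophil elastase (-0.54, adjusted p = 0.205). Without replicate 3 of the DBA/2J cross that list's median was -0.74, with camera adjusted p = 0.00130, and with the pancreatic covariate its adjusted p was 0.000665.

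Of 22 interferon response genes measured, 10 were higher in the AKR/J cross, 1 was higher in the DBA/2J cross and 11 did not pass (14 and 1 adjusted over the list alone). The 10 include Xaf1, which was 0.88 higher in the AKR/J cross at the probe set used for the list and differed by -3.29 at its other probe set. Rtp4 differed by 0.80 ± 0.10 (adjusted p = 0.00594), Ifit1 by 0.66 ± 0.09 (adjusted p = 0.00751) and the membrane tether Bst2 by 0.62 ± 0.09 (adjusted p = 0.00949), whereas Rsad2, which encodes the antiviral enzyme viperin, differed by -1.52 ± 0.21 (adjusted p = 0.00729). The list's median was 0.34 (camera adjusted p = 5.14e-05), with adjusted p = 0.570 with an estimated correlation. The count higher in the AKR/J cross was 3, 7 and 5 without replicates 1, 2 and 3 of the AKR/J cross, 13, 5 and 6 without replicates 1, 2 and 3 of the DBA/2J cross, and 4 with the pancreatic covariate.

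In the major histocompatibility complex, large differences were seen at H2-Ea and at some probe sets of H2-D1, and neither list of its genes was called. AKR/J carries the k haplotype of this complex, DBA/2J the d haplotype and FVB/NJ the q haplotype. H2-Ea, the alpha chain of a class II molecule, was higher in the DBA/2J cross at each of its 3 probe sets (-3.40 ± 0.10, -2.52 ± 0.13 and, near background, -0.41 ± 0.10). At the first of these H2-Ea stood at 12.84 ± 0.11 in the DBA/2J cross and 9.44 ± 0.12 in the AKR/J cross. The class I gene H2-D1 had 9 probe sets on the array. One of them was higher in the AKR/J cross by 5.82 ± 0.11 (adjusted p = 4.01e-07), and 3 were higher in the DBA/2J cross, by -5.25 ± 0.12, -3.34 ± 0.09 and -3.12 ± 0.10. The other 5 did not pass, among them the brightest, at 13.32 and 13.41 (-0.09 ± 0.08). In the class II list, 1 gene was higher in the AKR/J cross, H2-Ob (0.44), and 3 in the DBA/2J cross, H2-Ea, H2-Ab1 (-0.42) and H2-Eb1 (-0.27), out of 10. In the class I list, 4 of 13 were higher in the AKR/J cross, namely the immunoproteasome subunits Psmb8 and Psmb9 (0.41 each), the peptide transporter Tap2 (0.41) and H2-Q10 (1.04, a lower bound, with the DBA/2J cross at 3.57, near background), and 0 in the DBA/2J cross. Adjusted over the list alone, the class II list had 1 and 4 and the class I list 4 and 1, and the camera adjusted p was 0.226 and 0.236. That of the class II list was 0.0370 with dim genes left out and 0.0431 without replicate 2 of the DBA/2J cross. H2-Ob passed without replicate 1 of the DBA/2J cross and in no other fit with 1 array left out. The class II count higher in the DBA/2J cross was 1, 1 and 1 without replicates 1, 2 and 3 of the AKR/J cross and 2, 2 and 1 without those of the DBA/2J cross. Without replicates 1, 2 or 3 of the AKR/J cross 0 class I genes passed, and 1 passed without replicate 2 or 3 of the DBA/2J cross.

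**Figure D2:**
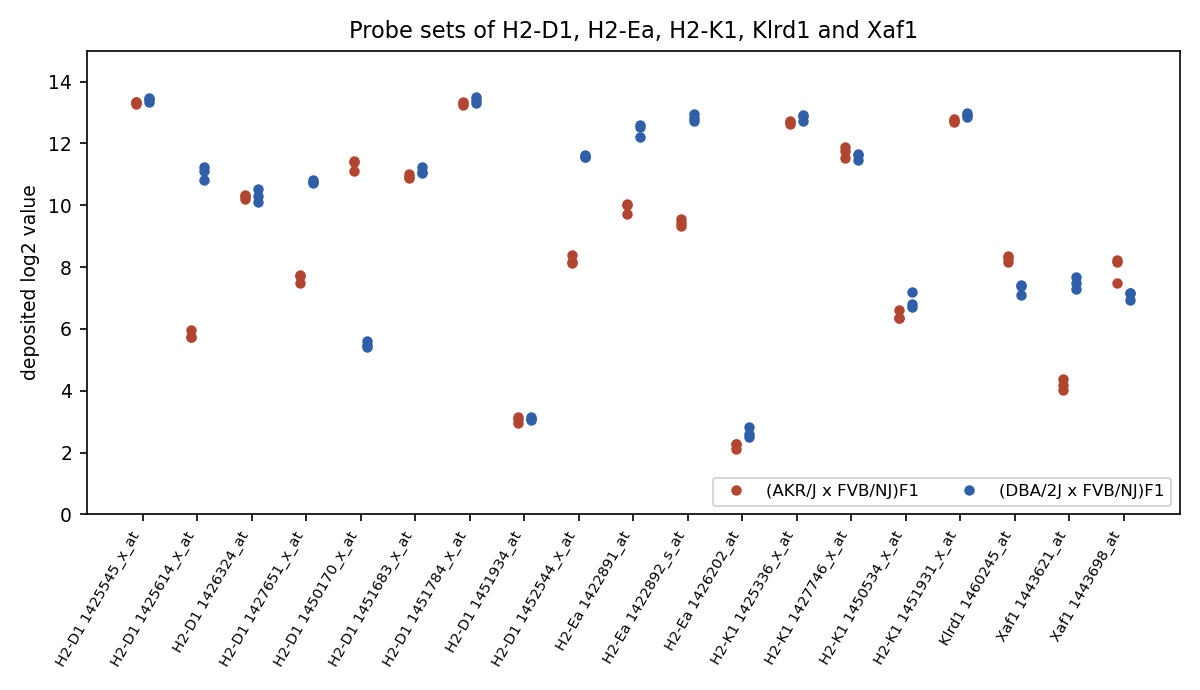
Deposited log2 values of each array (points, 3 per cross) for the probe sets of H2-D1, H2-Ea, H2-K1, Klrd1 and Xaf1. One H2-D1 probe set is higher in the AKR/J cross (11.31 against 5.50) and another is higher in the DBA/2J cross (11.05 against 5.81).

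H2-D1 was one of 44 genes, out of 525 with at least 2 probe sets past the threshold, whose probe sets passed in opposite directions. That number was 3, 4 and 6 without replicates 1, 2 and 3 of the AKR/J cross and 26, 4 and 6 without those of the DBA/2J cross. Xaf1, an interferon-induced gene of cell death, differed by -3.29 ± 0.13 at one probe set and 0.88 ± 0.19 at the other. Pdxdc1 differed by -2.40 ± 0.12 at one, and by 0.90 ± 0.08 and 0.40 ± 0.10 at others. Further large differences were seen at 1 of a gene's probe sets and were small or absent at the others. Tia1, an RNA-binding protein of stress granules, differed by 3.50 ± 0.15 at one probe set (adjusted p = 2.29e-05), a lower bound because it was near background in the DBA/2J cross (3.51). Its brightest probe set differed by 0.00 ± 0.08. Ssbp2 differed by 3.01 ± 0.10 at one and by 0.01 to -0.34 at the others, and the first is a lower bound, since that probe set was at background in the DBA/2J cross (2.59). The Polycomb group gene Scmh1 differed by 1.98 ± 0.14 at one probe set, a lower bound because it was near background in the DBA/2J cross (3.03), and by -0.01 and 0.17 at the others. For Tia1, Ssbp2 and Scmh1 the lower bound holds for the signal of that probe set and not for the gene's transcript as a whole. Sdc4, a cell surface proteoglycan, differed by 2.49 ± 0.15 at one probe set and 0.19 ± 0.09 at the other. Uqcr10, a subunit of respiratory complex III, differed by -2.34 ± 0.15 at a dim probe set and by -0.13 at the bright one. A further Uqcr10 probe set differed by -0.44 ± 0.09 (adjusted p = 0.0222 in limma). Itih4 (1.96 ± 0.12) and the muscle actinin gene Actn2 (1.94 ± 0.18) each had 1 probe set.

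Transcripts of the exocrine pancreas were present at very high levels in 5 of the 6 arrays. The median of 16 pancreatic acinar genes was 13.72, 13.71 and 13.77 in the AKR/J cross, 13.02 and 13.50 in replicates 1 and 2 of the DBA/2J cross, and 5.65 in its replicate 3. Carboxypeptidase A1 (Cpa1) stood at 14.03, 14.03 and 14.07 in the AKR/J cross and at 13.58, 13.88 and 5.92 in the DBA/2J cross. Of the 16 genes 0 passed in limma (also 0 adjusted over the list alone, and 2 at an unadjusted p under 0.05), and the one with the smallest p was the phospholipase gene Pla2g1b (2.52 ± 0.96, adjusted p = 0.102). The list was called higher in the AKR/J cross (median 2.99, camera adjusted p = 0.00612), with adjusted p = 0.785 with an estimated correlation, and without replicate 3 of the DBA/2J cross its median was 0.46 (camera adjusted p = 3.70e-07, 1 gene past the threshold). With dim genes left out its camera adjusted p was 0.132. Every AKR/J cross array lay above every DBA/2J cross array in the mean of the acinar list (13.36, 13.40 and 13.48 against 12.58, 13.11 and 5.80), and likewise for the genes that follow. Reg2 stood at 12.58, 13.09 and 12.71 in the AKR/J cross and at 6.53, 6.31 and 5.24 in the DBA/2J cross (6.77 ± 0.30, adjusted p = 3.67e-05). Reg3b differed by 6.54 ± 0.24 (adjusted p = 9.74e-06) and Reg3a by 4.17 ± 0.32 (adjusted p = 0.000647). In the DBA/2J cross they stood at 3.17 and 3.27, close to the absent Trp controls (2.55), so these 2 differences are lower bounds. Reg3d differed by 3.48 ± 0.68 (adjusted p = 0.0226), and by 2.53 without replicate 3 of the DBA/2J cross. The serine protease gene Prss22 stood at 8.45 ± 0.18 and 4.68 ± 0.19 (3.77 ± 0.13, adjusted p = 7.39e-06). Without replicates 1, 2 and 3 of the AKR/J cross the adjusted p of Reg3d was 0.0748, 0.0632 and 0.0659.

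**Figure D3:**
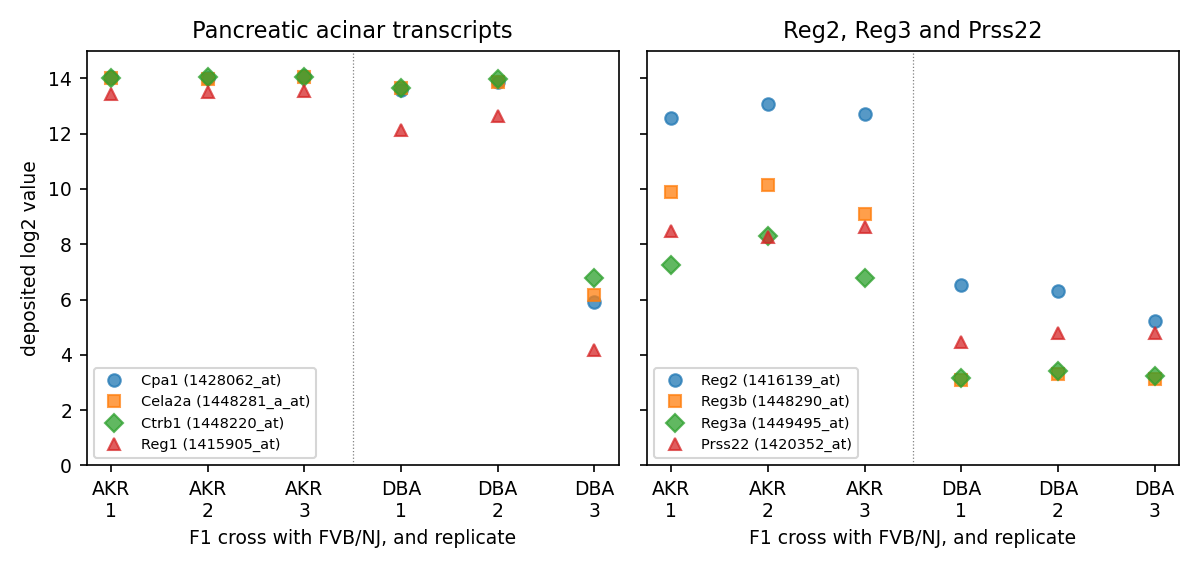
Deposited log2 values of pancreatic acinar transcripts (left) and of Reg2, Reg3b, Reg3a and Prss22 (right) in each of the 6 arrays. The acinar transcripts are high in all arrays except replicate 3 of the DBA/2J cross, where Cpa1 is at 5.92, and Reg2 is above 12.5 in the AKR/J cross and at most 6.53 in the DBA/2J cross.

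Of 31 extracellular matrix genes, 7 were higher in the AKR/J cross and 1 in the DBA/2J cross (8 and 3 adjusted over the list alone). The matricellular protein Postn differed by 1.43 ± 0.10 (adjusted p = 0.000507), the small proteoglycans Lum and Dcn by 1.13 ± 0.13 and 0.62 ± 0.14, and the collagen chain Col6a3 by -0.60 ± 0.13. The list's median was 0.15 (camera adjusted p = 0.0242), with adjusted p = 0.785 with an estimated correlation, with 2, 3 and 2 genes higher in the AKR/J cross without replicates 1, 2 and 3 of the AKR/J cross and 11, 2 and 2 without replicates 1, 2 and 3 of the DBA/2J cross. The list's adjusted p was 0.0762 without replicate 3 of the AKR/J cross and 0.0871 without replicate 2 of the DBA/2J cross, 0.387 with dim genes left out and 0.0867 after quantile normalization, where 3 genes were higher in the AKR/J cross. Of 8 megakaryocyte and platelet genes 0 passed in limma, also 0 adjusted over the list alone and 3 at an unadjusted p under 0.05, and the smallest p was that of the platelet glycoprotein Gp9 (-0.35, adjusted p = 0.0596). That list was called lower in the AKR/J cross (median -0.26, camera adjusted p = 0.0463), with adjusted p = 0.785 with an estimated correlation. Its adjusted p was 0.0853 and 0.133 without replicates 1 and 3 of the AKR/J cross and 0.306 without replicate 1 of the DBA/2J cross, and 0.141 with array weights. The adipocyte list was not called (camera adjusted p = 0.236), and 1 of its 8 genes passed, Pck1, a gluconeogenic enzyme, at a level near background (-0.44, also 1 adjusted over the list alone). Without replicate 1 of the AKR/J cross that list was called higher in the AKR/J cross (median 0.68, camera adjusted p = 0.0143), with 2 genes higher there. Pck1 passed without replicate 3 of the AKR/J cross and in no other fit with 1 array left out.

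In the immediate early, glucocorticoid response and heat shock lists 0 of 15, 11 and 10 genes passed in limma, also 0 adjusted over each list alone and 1, 1 and 0 at an unadjusted p under 0.05. The smallest p values belonged to Klf4 (0.50, adjusted p = 0.0532), Sgk1 (0.47, adjusted p = 0.0939) and Hspd1 (-0.32, adjusted p = 0.241). Their camera adjusted p was 0.369, 0.657 and 0.835. The median of the immediate early list was 0.05, and -0.03 after quantile normalization, and that of the glucocorticoid list was 0.13. The immediate early list was called higher in the AKR/J cross without replicate 3 of the DBA/2J cross (median 0.30, camera adjusted p = 0.0370) and with the pancreatic covariate (0.34, adjusted p = 0.0212). The heat shock list had a median of 0.09 and a mean of 0.02, while its test pointed down. In the ribosomal protein list, 4 of 57 genes were higher in the AKR/J cross and 2 in the DBA/2J cross (2 and 0 adjusted over the list alone), and the list was not called (adjusted p = 0.245, and 0.00710 with dim genes left out). Without replicates 1, 2 and 3 of the AKR/J cross 1, 3 and 1 were higher in the AKR/J cross, and without those of the DBA/2J cross 3, 3 and 2. In the same 6 fits 0, 0, 0, 0, 1 and 0 were higher in the DBA/2J cross. The ribosomal protein Rps6 differed by 0.54 ± 0.10 and Rps4l by 0.61 ± 0.15. Rpl3l differed by -0.37 ± 0.10 at a level near background (3.19 in the AKR/J cross and 3.57 in the DBA/2J cross). Rps6ka5 (0.50 ± 0.08), a kinase taken in by the name pattern, is not a ribosomal protein. In the oxidative phosphorylation list, 1 of 86 genes was higher in the AKR/J cross, Cox7c (0.65 ± 0.18), and 3 in the DBA/2J cross, Cox6b2 (-1.35 ± 0.27), Cox8c (-0.48 ± 0.07) and the assembly factor Ndufaf1 (-0.35 ± 0.10). Adjusted over the list alone, the counts were 0 and 2, and the list was not called (adjusted p = 0.236). Without replicates 1, 2 and 3 of the AKR/J cross 1, 2 and 1 genes of that list were higher in the DBA/2J cross, and 1 without replicate 2 or 3 of the DBA/2J cross. Cox7c passed in 5 of 13 alternatives. Without replicate 1 of the DBA/2J cross, 9 genes were higher in the DBA/2J cross and the list's adjusted p was 0.00255, and the adjusted p was 0.00997 after quantile normalization and 0.00166 with dim genes left out.

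Of 5 metastasis modifier genes, 2 were higher in the AKR/J cross: Arap3 (0.32 ± 0.08, adjusted p = 0.0370) and Sipa1, a Rap GTPase activator (0.28 ± 0.08, adjusted p = 0.0467). The values of Rrp1b (0.25), Nup210 (0.13) and Cadm1 (0.06, and -0.02 after quantile normalization) did not pass, and 3 passed adjusted over the list alone. The list's median was 0.25 (camera adjusted p = 0.0463), with adjusted p = 0.570 with an estimated correlation. Without replicates 1, 2 or 3 of the AKR/J cross or replicates 2 or 3 of the DBA/2J cross, 0 of its genes passed. Its adjusted p was 0.0586 and 0.0900 without replicates 2 and 3 of the AKR/J cross and 0.0938 and 0.0548 without replicates 1 and 2 of the DBA/2J cross. It was 0.109 after quantile normalization, 0.153 with dim genes left out and 0.0599 with array weights. With quantile normalization, the replicate block or the pancreatic covariate 0 of its genes passed, so Arap3 and Sipa1 lost their calls there. Of 8 genes known to vary between inbred strains, 2 were higher in the AKR/J cross (also 2 adjusted over the list alone, with 1 in the other direction): Klrd1 and the T cell surface glycoprotein Thy1 (0.38 ± 0.09, adjusted p = 0.0263). Thy1 passed without replicate 1 of the DBA/2J cross and in none of the other 5 fits with 1 array left out, where the count was 1. Gpnmb (-0.26), Tyrp1 (-0.21), Glo1 (-0.12), Hc (-0.08), Fv1 (0.03) and Xpr1 (-0.01) did not pass, and the sign of Xpr1 turned with median centring (0.03) and that of Hc with quantile normalization (0.02). That list was not called (adjusted p = 0.835), with a median of -0.04 against a mean of 0.09 and a test that pointed up. Xist, transcribed from the inactive X chromosome, stood at 11.27 and 11.32 in the 2 crosses, and the Y-linked genes Kdm5d, Uty and Eif2s3y lay between 2.44 and 2.89 on average, as in female tissue, with 0 of these 4 genes past the threshold in limma, also 0 adjusted over the list alone and 0 at an unadjusted p under 0.05.

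Neighbouring genes were examined because parental strains differ in blocks of sequence. Among the 3126 differing genes that could be placed in order, 563 pairs were direct neighbours, against 538 in random draws of as many genes (95% of draws between 500 and 575, one-sided permutation p = 0.0984). The longest runs held 6 genes. One was a run of the zinc finger genes Zfp995, Zfp942, Zfp943, Zfp994, Zfp944 and Zfp758, all higher in the AKR/J cross. The other held Pga5, Vps37c, Cd5, A430093F15Rik, Cd6 and Slc15a3, with 5 of the 6 higher in the AKR/J cross. The runs were picked after the values were seen, as the longest. The observed over expected ratio was 1.05, and 1.02 with pairs that share their first 3 letters left out (one-sided permutation p = 0.333). The ratio was 1.83, 1.31 and 1.49 without replicates 1, 2 and 3 of the AKR/J cross and 1.10, 1.48 and 1.30 without those of the DBA/2J cross, and it passed its test in each of these fits and in each other alternative except with family pairs left out.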

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

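All tests in this part were chosen after the results they weigh had been seen, and the samples are 3 against 3.

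The poly-A spike-in controls, added to the RNA before labelling and not used in any comparison, differed between the crosses. Their mean was 6.68 ± 0.06 in the AKR/J cross and 6.23 ± 0.12 in the DBA/2J cross (SD, n = 3 each), a difference of 0.456, with every AKR/J cross array above every DBA/2J cross array (exact permutation p = 0.1, the smallest that 3 against 3 can give, 2-sided). The hybridisation controls, added later, differed by 0.05 and overlapped. The 3' minus 5' difference of Gapdh, a measure of RNA quality and labelling, also separated the crosses (-0.17 ± 0.02 in the AKR/J cross and -0.23 ± 0.01 in the DBA/2J cross, exact permutation p = 0.1), and that of actin did not. A labelling batch that follows the cross therefore cannot be told apart from the cross, because no date or batch is given.

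The Reg2, Reg3a, Reg3b and Reg3d transcripts were far higher in the AKR/J cross. Without replicate 3 of the DBA/2J cross, the median difference of the 5 Reg probe sets was 4.66 (median SE 0.28). In that fit 16 pancreas-derived probe sets below log2 11 had a median of 1.25 and a highest value of 1.68. These 16 were picked from the same arrays by a drop of at least 3 in replicate 3 of the DBA/2J cross. Reg3a and Reg3b stood near background throughout that cross, and a reference picked by such a drop may leave out patterns like theirs. The 5 Reg probe sets were taken because they passed. Reg1, of the same family, followed the acinar transcripts (12.13, 12.64 and 4.16 in the DBA/2J cross) and did not pass. The 5 thus differed by more than transcripts that followed the acinar ones. For these reasons the comparison cannot decide whether more admixed pancreatic tissue in the AKR/J cross was involved. A different state of the pancreatic tissue or of the spleen stays open: the lowest mean of pancreatic transcripts in an AKR/J cross array was 13.36 on the log2 scale, so no array of that cross shows Reg expression without them. The parental strains themselves are a further, untested explanation.

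Erythroid and cell cycle transcripts were higher in the DBA/2J cross, in camera as lists only at the preset correlation (adjusted p = 0.570 each with an estimated one). With fry the erythroid list passed (adjusted p = 0.0281) and the cell cycle list did not (adjusted p = 0.0722). Dilution of spleen RNA by pancreatic RNA would lower T cell and erythroid transcripts alike, yet the T cell score minus the erythroid score shifted by 2.08 (SE 0.30). A lower share of lymphocytes alone would raise macrophage and erythroid transcripts alike in the DBA/2J cross, yet the macrophage score minus the erythroid score shifted by 1.76 (SE 0.31). A labelling batch stays open through the spike-in difference of 0.456. More red cell formation in spleens of the DBA/2J cross is a candidate explanation that these arrays did not test.

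H2-D1 probe sets past the threshold moved in opposite directions, with 11.1 on the log2 scale between the highest and the lowest. One change in the total amount of the transcript cannot give opposite signs. Probe binding that differs with the parental sequence may be involved: of 23 probe sets with at least a 4-fold difference and another bright probe set for the gene, 13 (56.5%, Clopper-Pearson 95% confidence interval 34.5 to 76.8%) had a difference that the other bright probe sets did not share. The 23 include probe sets of H2-D1 itself, and probe sets of the same gene are not independent. The share and its interval therefore cannot decide the question. Transcript forms that differ between the strains would give the same picture, and probe sequences were not used here.

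Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 4688 probe sets, 2317 higher in the AKR/J cross and 2371 higher in the DBA/2J cross, 1502 of at least 1.5-fold and 3133 genes, and the highest of the other splits gave 0 of each, so 1 of the 10 splits reached each count. For gene lists the real split gave 11 and the highest other 15, and 5 of the 10 splits, the real one included, gave as many.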

How the results depend on the processing

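The pancreatic covariate was chosen after the data were seen. Of the 24 named genes, 22 kept direction and call in every alternative run for them, and Reg3d and Tac2 lost the call in some. Of the 54 named list genes past the threshold, which include Rhd, Rhag and H2-Ea of the 24, 23 kept the call in every alternative and 31 lost it in some. Named list genes are those with the smallest adjusted p in each list, and further list genes past the threshold were not counted here. Of the 11 lists called, 5 kept the call in every alternative other than the set test and 6 lost it in some. The number of lists called was 0 with an estimated correlation and 5 with fry, which test different statements.

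Quantile normalization gave 1434 probe sets higher in the AKR/J cross, 1860 genes and 20 genes with opposite probe sets, and array weights gave 74 of the latter. The neighbour ratio passed its test with median centring (1.08), quantile normalization (1.18), dim probe sets left out (1.06), the trended variance (1.06), array weights (1.05) and the replicate block (1.09). With the replicate block 4658 probe sets passed, 3731 of them shared with the 4688, and the calls of all lists were as without it. Of the named list genes, 9 were no longer past the threshold (Arap3, Sipa1, Klra7, Derl3, H2-Eb1, Rps4l, Rpl3l, Cox7c and Ndufaf1), while Klf4 was. The labels name no pairing. Residuals of equal replicate numbers had r of 0.20, 0.11 and 0.05 across probe sets, those of unequal numbers -0.16 to 0.06, and 5 of the 6 samples correlated best with their own number in the other cross, a hint from the data and not from the design. The cause was not tested for any of these.

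With the pancreatic covariate, which costs 1 residual degree of freedom, 781 probe sets passed (413 and 368), 755 of them shared with the 4688, 700 of at least 1.5-fold, with 576 genes, 6 genes with opposite probe sets and a neighbour ratio of 1.82.

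Leaving out 1 array leaves fewer samples. Probe sets ranged from 1001 to 4793 (514 to 2286 higher in the AKR/J cross, 487 to 2507 in the DBA/2J cross), those of at least 1.5-fold from 786 to 2068, genes from 672 to 3454, genes with opposite probe sets from 3 to 26, and the neighbour ratio from 1.10 to 1.83.

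All sign changes concerned values that had not passed, except the acinar list, whose own mean was the covariate (-0.13). With median centring Xpr1 was 0.025 and Eif2s3y 0.0066. With quantile normalization macrophages were -0.013, immediate early genes -0.031, Cadm1 -0.021, Hc 0.025 and Eif2s3y 0.013. Glucocorticoid response was -0.00092 with array weights, oxidative phosphorylation 0.0099 with the covariate and known strain variants 0.0042 with the mean of a gene's probe sets. With 1 array left out in turn, values ranged from -0.013 to 0.10 for macrophages, -0.74 to 0.17 for neutrophils, -0.11 to 0.30 for immediate early genes, -0.30 to 0.34 for glucocorticoid response, -0.29 to 0.14 for heat shock and -0.10 to 0.0023 for oxidative phosphorylation. They ranged from -0.035 to 0.15 for Cadm1, -0.0057 to 0.093 for Fv1, -0.058 to 0.047 for Xpr1, -0.16 to 0.021 for Uty and -0.057 to 0.019 for Eif2s3y. The cause was not tested. Signal over background limits transcripts near the low end, such as those of the Y-linked genes.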

Other observations

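The gene groups and tests in this part were chosen after the results had been seen. Genes of heme synthesis were higher in the DBA/2J cross for 6 of 7 measured (median -1.11), among them Alad (-1.50 ± 0.25), Urod (-1.31 ± 0.18) and Fech, which inserts iron into the heme ring (-1.11 ± 0.14), while Cpox (-0.85 ± 0.26) did not pass. Genes of the red cell membrane skeleton were higher in the DBA/2J cross for 6 of 6 (median -1.75), among them Dmtn (-1.95 ± 0.26), the spectrin chain Sptb (-1.66 ± 0.22) and the ankyrin Ank1 (-1.60 ± 0.22). Erythroid transcription factors were higher in the DBA/2J cross for 7 of 8 (median -1.32), among them Klf1 (-1.96 ± 0.36), Tal1 (-1.69 ± 0.25) and Nfe2 (-1.54 ± 0.17), and Ldb1 (0.13 ± 0.08) did not pass. Alas2, Epb42, Gata1 and Klf1 belong to these groups and to the erythroid list as well.

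Klrd1 was lower in the DBA/2J cross by a log2 difference of 0.97 (95% confidence interval 0.72 to 1.22), and DBA/2J mice are known to lack its product CD94. A single inactive copy inherited from DBA/2J may therefore account for the size of the difference, since it would halve the amount. The size alone cannot decide this, since the T cell and NK cell lists were also higher in the AKR/J cross (medians 0.42 and 0.25). Klrd1 is itself in the NK cell list. Weaker probe binding to the DBA/2J copy is not excluded, and Klrd1 has 1 probe set.

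Among the 500 genes with the smallest p, 26 neighbouring pairs were found against 13.6 in random draws, a ratio of 1.91 (one-sided permutation p = 0.0011), with Cd8b1 and Cd8a, Reg3a and Reg2, and Vps37c and Cd5 among them. Inherited differences that act on neighbouring genes may contribute. The count of pairs cannot decide this, since Cd8b1, Cd8a and Cd5 also belong to the T cell list, whose genes were higher in the AKR/J cross. For these 500 genes, gene families side by side did not account for the excess alone, since the ratio was 1.84 with pairs that share their first 3 letters left out (23 pairs, permutation p = 0.0035). That depends on the number of genes taken. For the 250 genes with the smallest p the ratios were 2.97 with all pairs (permutation p = 0.0028) and 2.25 without family pairs, where the 7 pairs lay at the upper end of 95% of draws (0 to 7, permutation p = 0.0389). For 1000 genes they were 1.28 (permutation p = 0.0206) and 1.18 (permutation p = 0.111).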
